A study of Mus musculus with 18 samples.

How the data were processed

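RNA from cultured mouse neurons was measured on 18 Illumina MouseRef-8 v2.0 bead arrays. The neurons received adaptaquin, an inhibitor of the HIF prolyl hydroxylases, at 0, 0.1 or 1 µM, each with or without homocysteic acid (HCA), a glutamate analogue that depletes glutathione and brings about oxidative death. These 6 groups had 3 arrays each. Per the labels, total RNA was taken up in Trizol, cleaned on a column with DNase I, checked on a Bioanalyser, and turned into biotinylated cRNA with an Ambion kit. The title of the third HCA-only array marks it as an outlier, and it was left out of the fit described here, so that the HCA-only group had 2 arrays and every other group 3. The labels do not state that replicates were separate cultures, so p-values of single genes measure the spread between these samples, which may be technical.

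The authors deposited a table of probe intensity for all 18 arrays, not normalized between arrays. The deposited table also holds a detection p-value for each probe on each array. A further table by the authors holds log2 values for 17 arrays. Those log2 values equalled a plain quantile normalization of the deposited intensities to within 5.0e-09, every column having a median of 7.37. The scanner software and any upstream filter are not given in the sources used here.

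Intensities were background-corrected from the detection p-values, offset by 16, quantile-normalized over the 18 arrays together and put on the log2 scale with the neqc function of limma 3.58.1 in R 4.3.3. Of 25697 probes, 23978 had 1 gene symbol and 1719 had none. Symbols were taken from a table of probes and genes for these arrays. Of them, 23962 were matched by gene identifier to a RefSeq gene table of GRCm38.p6, which changed 0 symbols. Whether the first table had already been brought to those names is not known. Probes with a detection p-value under 0.01 on at least 2 of the 17 arrays were kept, which gave 12991 probes, 12227 of them with a symbol. The brightest probe stood for each gene, and 2386 genes had more than 1 probe, leaving 8922 genes. No coordinates are given, since no genome build is named with the arrays.

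A linear model with 1 coefficient for each of the 6 groups was fitted with limma and moderated with its empirical Bayes method, with 11 residual and 3.22 prior degrees of freedom. The tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method within each of 11 contrasts, with a threshold of 0.05. The contrasts were the HCA effect at each adaptaquin dose, the effect of each adaptaquin dose without and with HCA, the difference between the doses without and with HCA, and the interaction of HCA with each dose. Changes are given as log2 fold change with its standard error. Where a gene was not above background on any array of 1 group, its change is given as at least N-fold, measured from the other group's mean down to the dimmest level detected on each array of the first group or to the gene's own value where that was higher, and no fold is given under 1.

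Before the data were examined, 23 gene lists, the contrasts, the rule for naming genes and most of the other settings were fixed. The lists held targets of ATF4 and CHOP, aminoacyl-tRNA synthetases, HIF targets, the prolyl hydroxylases with their transcription factors, NRF2 targets, glutathione genes, endoplasmic reticulum chaperones, p53 targets, cell death genes, cholesterol genes, immediate early genes, heat shock genes, iron and metallothionein genes, respiratory chain genes and interferon genes. Further lists held markers of neurons, GABAergic neurons, astrocytes, microglia, oligodendrocytes, vessel and fibroblast cells, proliferating progenitors and red blood cells. The red blood cell list was not tested, since only 1 member was measured. The other 22 were tested against all other genes with camera of limma, at a preset correlation of 0.01, adjusted over the 22 lists of a contrast, and again with an estimated correlation. The list of ATF4 and CHOP targets shared 4 members with the glutathione list and 2 with the NRF2 list. At the preset correlation a list p-value rests on the spread across genes and not between arrays. A list score is the mean log2 intensity of the members on an array. An exact permutation test of a score between arrays cannot give a p under 0.1 with 3 against 3 or 2 against 3. It gave 0.1 for the ATF4 list in each HCA effect and for the p53 list at 1 µM without HCA.

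The rule named the 10 largest called rises and falls of each contrast among genes whose groups did not overlap. Where none passed, it named the 3 genes with the smallest p. It added up to 4 members with the largest change of each list described, and 18 genes of the ATF4, HIF, p53, oxidative and iron responses in every contrast, of which Bnip3 did not pass the filter. Genes with provisional symbols were counted but not named. The texts give the few named genes that matter most and count the rest.

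Replicate numbers paired the arrays. In residuals from the group means, the 40 pairs of arrays with the same number had a median correlation across genes of 0.438 and a lowest of 0.238, against a median of -0.241 for different numbers, and all 17 arrays were closest to arrays of their own number. A fit with the replicate number as a block was planned and is called the blocked fit.

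The other settings chosen at that point were all 18 arrays, all 18 with array weights, the blocked fit, no background correction, median scaling, the authors' table, no filter on dim probes, detection on every array, the mean of a gene's probes, all probes, the groups of the contrast only, an estimated correlation, and each array left out in turn. Chosen after the data were seen were the 17 arrays normalized alone, each replicate number left out, the blocked fit with all 18 arrays, and the blocked fit with an estimated correlation.

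The steps were tested on simulated data with 200 changed genes among 8922 in 10 runs. With 2 arrays against 3, 29.3% of changes of 0.5 on the log2 scale were recovered, 80.6% of changes of 1 and 98.0% of changes of 2, and 5.5% of calls were false. With 3 against 3, the shares were 42.7%, 85.7% and 98.8%, with 5.2% of calls false. A simulated shift of 0.3 in the p53 list was called in 10 of 10 runs in both designs. The simulated genes varied independently, with no replicate effects and no correlation between list members. The shares and list calls therefore do not cover the pairing and member correlation of the real arrays. The number of arrays limits the precision of every value. Tables were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.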

Results

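The data were 18 bead arrays of RNA from cultured mouse neurons in 6 groups of 3. The groups were untreated neurons, neurons with 0.1 or 1 µM adaptaquin, neurons with homocysteic acid (HCA), and neurons with HCA and 0.1 or 1 µM adaptaquin. The series title concerns adaptaquin, ATF4-dependent death and brain haemorrhage. On the 17 arrays used, the upper quartile of probe intensity lay between 333 and 563, and 42.8% to 47.6% of probes were detected. The HCA-only array titled as an outlier had an upper quartile of 241 and 40.9% detected, and it was not used here unless stated. The number of arrays limited the precision.

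The first comparison asked what HCA did to neurons without adaptaquin (2 HCA arrays, 3 untreated). Targets of the amino acid response and genes of neuronal activity were among the largest rises. Chac1, an enzyme that breaks down glutathione, rose by 2.26 ± 0.18 on the log2 scale (adjusted p = 2.6e-05), from a mean of 10.32 to 12.58. Slc7a3, a transporter of cationic amino acids, rose by 2.97 ± 0.33 (adjusted p = 2.6e-04). Sesn2, a stress-induced inhibitor of mTORC1 signalling, rose by 1.96 ± 0.16, and Stc2, a secreted stress protein, rose by 2.16 ± 0.18. Some genes induced by neuronal activity also rose, namely the transcription factors Npas4 (2.79 ± 0.27) and Fos (2.73 ± 0.28) and the growth factor gene Bdnf (2.13 ± 0.24).

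Of 29 measured targets of ATF4 and CHOP, the transcription factors of the amino acid and endoplasmic reticulum stress responses, 18 rose over all genes and 25 when adjusted over the list alone. All 29 values were positive, with a median of 1.16 (list adjusted p = 7.3e-53). The glycine transporter Slc6a9 rose by 1.97 ± 0.23 and Ddit3, which encodes CHOP, by 0.76 ± 0.14 (adjusted p = 0.018). The pseudokinase gene Trib3 was at least 1.04-fold higher (means 5.73 and 4.82, adjusted p = 0.029). The gene of ATF4 itself, which is controlled largely at translation, had a value of 1.33 ± 0.33 and did not pass (adjusted p = 0.087), but passed in the blocked fit (8.6e-04). Ddit4, another inhibitor of mTORC1 signalling, had a value of 0.67 ± 0.18 (adjusted p = 0.12, blocked 4.1e-04). Of 18 aminoacyl-tRNA synthetases, which charge tRNAs for translation, 3 rose over all genes and 10 adjusted over the list alone, with a median of 0.44 (list adjusted p = 8.2e-09). Mars1 rose by 0.85 ± 0.16 and Aars by 0.79 ± 0.15.

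Of 19 glutathione genes, 4 rose over all genes and 4 adjusted over the list alone (median 0.15, list adjusted p = 9.7e-05), and the 4 are also ATF4 targets. They were Chac1, the cystine and glutamate exchanger gene Slc7a11 (1.81 ± 0.20), its partner Slc3a2 (1.28 ± 0.21), and Cth, which makes cysteine and was at least 1.80-fold higher (means 6.51 and 4.83). Of 18 immediate early genes, 3 rose over all genes and 7 adjusted over the list alone (median 0.38, list adjusted p = 1.1e-07). Other members did not pass, such as Arc (-0.27), Inhba (-0.34), Egr1 (0.069), Egr3 (0.034) and Homer1 (0.078). The immediate early list did not pass in the blocked fit with an estimated correlation (median 0.37, adjusted p = 0.0706), and its median was 0.22 without HCA replicate 2. The median of 17 cholesterol genes was 0.28, 16 values were positive, and 0 rose by either adjustment (list adjusted p = 3.4e-05 with limma's camera, adjusted p = 0.213 with an estimated correlation). Of 18 p53 targets, 1 rose over all genes and 3 adjusted over the list alone (median 0.32, list adjusted p = 0.030, adjusted p = 0.147 with an estimated correlation). The 1 gene was Plk3, a stress-response kinase (0.58 ± 0.12), while the cell cycle inhibitor gene Cdkn1a had a value of 0.71 ± 0.21 (adjusted p = 0.17, blocked 4.5e-03). Of 16 markers of proliferating progenitors, 15 values were negative, with a median of -0.34, and 0 fell over all genes against 2 adjusted over the list alone (list adjusted p = 2.6e-04, adjusted p = 0.439 with an estimated correlation). The stem cell filament gene Nes had a value of -0.68 ± 0.19 (adjusted p = 0.13, blocked 3.2e-03).

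The measured HIF targets as a list did not pass. Of 29, 1 rose, 0 fell, and the median was 0.039 (list adjusted p = 0.49, 1 up and 2 down adjusted over the list alone). The riser was Vegfa, a growth factor for vessels that ATF4 also induces (1.13 ± 0.17, adjusted p = 3.4e-03). The prolyl hydroxylase genes Egln1, Egln2 and Egln3 had values of 0.074, -0.31 and -0.51, and Hif1a had 0.13 ± 0.20. Of 22 NRF2 targets, 1 rose, Slc7a11, and the median of -0.032 differed in sign from the mean of 0.095 and the test (list adjusted p = 0.60, 2 up adjusted over the list alone). Hmox1, a haem-degrading enzyme and NRF2 target, had a value of 1.16 ± 0.31 (adjusted p = 0.12, blocked 0.011). The transferrin receptor gene Tfrc rose by 0.77 ± 0.15, the 1 riser of 14 iron genes (median 0.084, 2 up and 2 down adjusted over the list alone). Herpud1, a gene of endoplasmic reticulum-associated degradation, rose by 0.77 ± 0.10, the 1 riser of 14 chaperone and degradation genes (median 0.077, list adjusted p = 0.052, 1 up adjusted over the list alone). Of 11 astrocyte markers, 1 rose, the glutamate transporter gene Slc1a2 (1.98 ± 0.35, adjusted p = 0.014). The list median was -0.24, with 1 up and 1 down adjusted over the list alone (list adjusted p = 0.22, blocked 0.037). The oligodendrocyte score differed by -0.22 with no overlap of the groups (list adjusted p = 0.24).

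Over all genes, 54 rose and 13 fell. The falls were led by Pdzph1 (-1.71 ± 0.36), Fam53b (at least 1.94-fold lower, means 5.45 and 6.47), the histone gene H2ac7 (-0.86 ± 0.16), Fam221a (-0.78 ± 0.13) and the histone deacetylase gene Hdac1 (-0.68 ± 0.14). The blocked fit called 141 up and 111 down. The split was 80 up and 34 down with no background correction, 80 and 35 in the authors' table, and 38 and 1 with median scaling. The count of 67 became 25 without HCA replicate 1, 29 without HCA replicate 2, 44 without untreated replicate 2 and 41 without untreated replicate 3, and it was 114 with the titled outlier included. Without all arrays numbered 1, 2 or 3 it was 18, 7 or 37.

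With 0.1 µM adaptaquin present throughout, HCA again raised ATF4 targets and some immediate early genes (3 arrays against 3). Chac1 rose by 2.47 ± 0.16 (adjusted p = 3.0e-06), Fos by 3.11 ± 0.25, Slc7a3 by 2.97 ± 0.29, and Npas4 was at least 6.14-fold higher (means 8.22 and 4.93). Eif4ebp1, a translational repressor, rose by 1.81 ± 0.14, Slc7a11 by 1.66 ± 0.18 and Sesn2 by 1.74 ± 0.15. Atf4 rose by 1.25 ± 0.29 (adjusted p = 0.047), Hmox1 by 1.37 ± 0.28, Vegfa by 1.32 ± 0.15, Ddit4 by 0.70 ± 0.16 and Ddit3 by 0.60 ± 0.13. Trib3 was at least 1.00-fold higher (means 5.60 and 4.75). Egln3, a prolyl hydroxylase gene that HIF itself induces, fell by 0.80 ± 0.13 (adjusted p = 4.4e-03), and the HIF target Ndrg1 fell by 0.52 ± 0.092.

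Of 29 ATF4 and CHOP targets, 20 rose over all genes and 26 adjusted over the list alone (median 1.01, list adjusted p = 9.0e-50). Of 18 tRNA synthetases, 8 rose over all genes, and 11 rose and 1 fell adjusted over the list alone (median 0.47, list adjusted p = 2.2e-10). The immediate early list had 5 of 18 rises, 8 adjusted over the list alone (median 0.36, list adjusted p = 1.2e-10), and the glutathione list 4 of 19 by both (median 0.12, list adjusted p = 1.9e-03). The cholesterol list had 0 rises over all genes and 3 adjusted over the list alone, with 17 of 17 values positive (median 0.27, list adjusted p = 5.4e-05, adjusted p = 0.205 with an estimated correlation). Among 16 progenitor markers, Nes fell by 0.85 ± 0.17, and 3 fell adjusted over the list alone (median -0.34, list adjusted p = 3.1e-05, adjusted p = 0.266 with an estimated correlation). Of 11 astrocyte markers, 0 fell over all genes and 6 adjusted over the list alone, while Slc1a2 rose by 2.11 ± 0.31 (median -0.45, list adjusted p = 0.014, adjusted p = 0.205 with an estimated correlation). The scores of microglia (0.19) and oligodendrocyte (-0.19) markers also differed with no overlap of the groups, and neither passed as a list (list adjusted p = 0.13 and 0.24). The p53 list had 1 riser over all genes, Plk3, and 3 adjusted over the list alone (median 0.22, list adjusted p = 0.044, adjusted p = 0.201 with an estimated correlation).

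Over all genes, 114 rose and 56 fell at 0.1 µM. The falls included Bcan, which encodes the brain matrix protein brevican (-1.68 ± 0.27), Mc4r, a melanocortin receptor (at least 2.82-fold lower, means 5.10 and 7.12), Pdzph1 (-1.61 ± 0.32) and the metallothionein gene Mt3 (-0.65 ± 0.15). The blocked fit called 300 up and 233 down, and median scaling 48 up and 6 down. The total of 170 became 94, 86 and 92 without replicates 1, 2 and 3 of the 0.1 µM group. Without replicates 1, 2 and 3 of the group with HCA and 0.1 µM it became 112, 81 and 88, and without all arrays numbered 1, 2 or 3 it was 38, 22 or 55.

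With 1 µM adaptaquin present throughout, HCA raised Chac1 by 2.27 ± 0.16 (adjusted p = 9.6e-06), Slc7a3 by 2.71 ± 0.29, Slc7a11 by 1.82 ± 0.18 and Eif4ebp1 by 1.89 ± 0.14 (3 arrays against 3). Nupr1, a stress-induced chromatin protein gene, rose by 2.12 ± 0.38, Vegfa by 1.11 ± 0.15 and Sesn2 by 0.70 ± 0.15. Npas4 rose by 2.60 ± 0.24, Fos by 2.68 ± 0.25 and Slc1a2 by 2.20 ± 0.31. Not passing were Atf4 (0.98 ± 0.29, adjusted p = 0.15, blocked 4.2e-03), Ddit3 (0.52 ± 0.13, adjusted p = 0.072, blocked 0.033) and Hmox1 (0.79 ± 0.28, adjusted p = 0.24, blocked 0.035). Tfrc and Cdkn1a had values of 0.076 and -0.27, and Trib3 was not above background in either group.

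Of 29 ATF4 and CHOP targets, 17 rose over all genes and 24 adjusted over the list alone (median 0.86, list adjusted p = 2.0e-47), and of 18 tRNA synthetases 7 rose over all genes, with 10 up and 1 down adjusted over the list alone (median 0.46, list adjusted p = 8.7e-09). Of 18 immediate early genes, 3 rose, and 7 adjusted over the list alone (median 0.29, list adjusted p = 2.1e-08). Of 17 cholesterol genes 2 rose, among them the sterol oxidase gene Msmo1 (0.68 ± 0.15), and 4 adjusted over the list alone (median 0.26, list adjusted p = 6.2e-08, adjusted p = 0.095 with an estimated correlation). The glutathione list had 3 risers of 19 but did not pass as a list (median 0.046, list adjusted p = 0.067). The p53 list had 0 changes over all genes in limma and 0 adjusted over the list alone (median -0.063, list adjusted p = 0.45). The cell death list had 13 of 17 values negative and 0 called genes (median -0.16, list adjusted p = 0.029, adjusted p = 0.086 with an estimated correlation, blocked 0.068). Progenitor markers had 0 falls over all genes and 2 adjusted over the list alone (median -0.19, list adjusted p = 9.1e-03, adjusted p = 0.535 with an estimated correlation). Astrocyte markers had a median of -0.36, with 1 up and 1 down adjusted over the list alone (list adjusted p = 0.067, blocked 0.030). The GABAergic neuron score was higher by 0.12 with no overlap of the groups (list adjusted p = 0.21).

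Over all genes, 74 rose and 32 fell at 1 µM. The falls were led by Bcan (-1.80 ± 0.27), Pdzph1 (-1.54 ± 0.32), Loxl1, which encodes an enzyme that cross-links elastin (-0.98 ± 0.17), and Ass1, a urea cycle enzyme gene (-0.91 ± 0.14). The blocked fit called 221 up and 181 down, and median scaling 37 up and 5 down. The total of 106 became 55 and 52 without replicates 2 and 3 of the 1 µM group and 45 and 46 without replicates 2 and 3 of the group with HCA and 1 µM. Without all arrays numbered 1, 2 or 3 it was 43, 15 or 25.

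The HCA response was shared across the doses. Of the genes called without adaptaquin, 59 were also called at 0.1 µM, where independent lists would share 0.77, and 46 were called at 1 µM, where 0.49 would be shared. The 0.1 and 1 µM effects shared 75 called genes, against 1.15. These counts and expectations are for genes called in the same direction. The effects share no array within a pair, and across genes, which are not independent replicates, their Pearson correlations were 0.639, 0.653 and 0.705. The 170 genes called at 0.1 µM were used to score the other arrays, a score chosen after values had been seen. Their mean change in the HCA direction was 0.77 without adaptaquin and 0.70 at 1 µM, or 91.0%, with 168 of the 170 genes keeping their sign in both. Within replicate numbers 1 and 2 it was 0.65 and 0.83 without adaptaquin and 0.57 and 0.78 at 1 µM.

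Adaptaquin at 1 µM without HCA raised p53 target genes (3 arrays against 3). Cdkn1a rose by 1.52 ± 0.19 (adjusted p = 3.9e-03), from a mean of 9.04 to 10.56. The p53-induced genes Phlda3, an inhibitor of Akt signalling, and Ccng1, a cyclin, rose by 1.51 ± 0.18 and 1.06 ± 0.17, and the exonuclease gene Aen rose by 0.97 ± 0.17. Of 18 p53 targets, 4 rose over all genes and 10 adjusted over the list alone, 16 values were positive, and the median was 0.44 (list adjusted p = 1.7e-22). With median scaling and an estimated correlation the list did not pass (median 0.35, adjusted p = 0.0603). The mean change of the list score went from 0.54 ± 0.066 (SE) to 0.46 ± 0.16, the mean of all genes moved by -0.074, and the rise over all genes stayed near its value (0.55 and 0.54), while the estimated correlation between members went from 0.0197 to 0.472. Microglia markers were lower in the same arrays, with a score difference of -0.15 and no overlap of the groups, and did not pass as a list (median -0.12, list adjusted p = 0.060). Fas, a death receptor gene and p53 target, had a value of 1.21 ± 0.31 (adjusted p = 0.47, blocked 1.5e-03). The apoptosis genes Bbc3 and Pmaip1 did not pass, with a value of 0.42 for Bbc3, and Pmaip1 at least 1.15-fold higher (means 5.87 and 5.02). Nor did the p53 targets Mdm2 (0.18), Ddb2 (0.0026), Sesn1 (-0.059) and Rrm2b (-0.14).

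Other genes that rose with 1 µM were Tfrc (1.08 ± 0.13, adjusted p = 3.9e-03), whose mRNA is stabilised when cells sense low iron, Sesn2 (0.82 ± 0.15, adjusted p = 0.044), Ddit4l (1.42 ± 0.19), Pqlc3 (1.46 ± 0.25), Ephx1, a detoxifying hydrolase gene and NRF2 target (1.29 ± 0.22), Dcxr (1.19 ± 0.16) and Cox6b2 (1.05 ± 0.15). Measured genes of the HIF pathway did not pass. Of the 39 HIF targets fixed, 29 were tested. Bnip3, Car9, Car12, Adm, Pfkfb3, Epo, Higd1a and Gbe1 did not pass the filter, and Ankrd37 and Ero1l were not named on the array. Of 29 HIF targets, 0 were called in limma, over all genes or adjusted over the list alone, with a median of 0.024 (list adjusted p = 0.21). That list was called with a median of 0.080 without replicate 2 of the 1 µM group (adjusted p = 0.035). Vegfa had a value of -0.17, Egln1 of -0.037, Egln2 of 0.088, Egln3 of -0.14 and Hif1a of -0.25, and the list of the prolyl hydroxylases with their transcription factors had a median of -0.048 (list adjusted p = 0.52).

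Of 29 ATF4 and CHOP targets, Sesn2 rose and 0 fell over all genes, with 2 down adjusted over the list alone, a median of -0.11 and 20 negative values (list adjusted p = 0.013, adjusted p = 0.240 with an estimated correlation). That list call was also lost without untreated replicate 1 (adjusted p = 0.250), without replicate 2 (0.0596) or 3 (0.0828) of the 1 µM group, and without all arrays numbered 1 (0.144) or 3 (0.0656), with medians from -0.15 to -0.057 over the arrays left out. Chaperone and degradation genes of the endoplasmic reticulum had 13 of 14 negative values and 0 called members by either adjustment (median -0.13, list adjusted p = 7.4e-03, adjusted p = 0.363 with an estimated correlation). Single values were -0.058 for Atf4, -0.27 for Chac1, -0.64 ± 0.18 for Slc7a11, 0.10 for Ddit3 and 0.52 for Hmox1, none of which passed.

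Over all genes, 13 rose and 0 fell at 1 µM, and limma gave 198 genes with an unadjusted p under 0.05. That is fewer than a share of 0.05 of the 8922 genes, and the blocked fit gave 448. The blocked fit called 18 up and 3 down, and median scaling called 0. The count became 6, 8 and 4 without untreated replicates 1, 2 and 3, and 6 and 5 without replicates 1 and 2 of the 1 µM group. It was 0, 0 and 4 without all arrays numbered 1, 2 or 3.

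**Figure D1:**
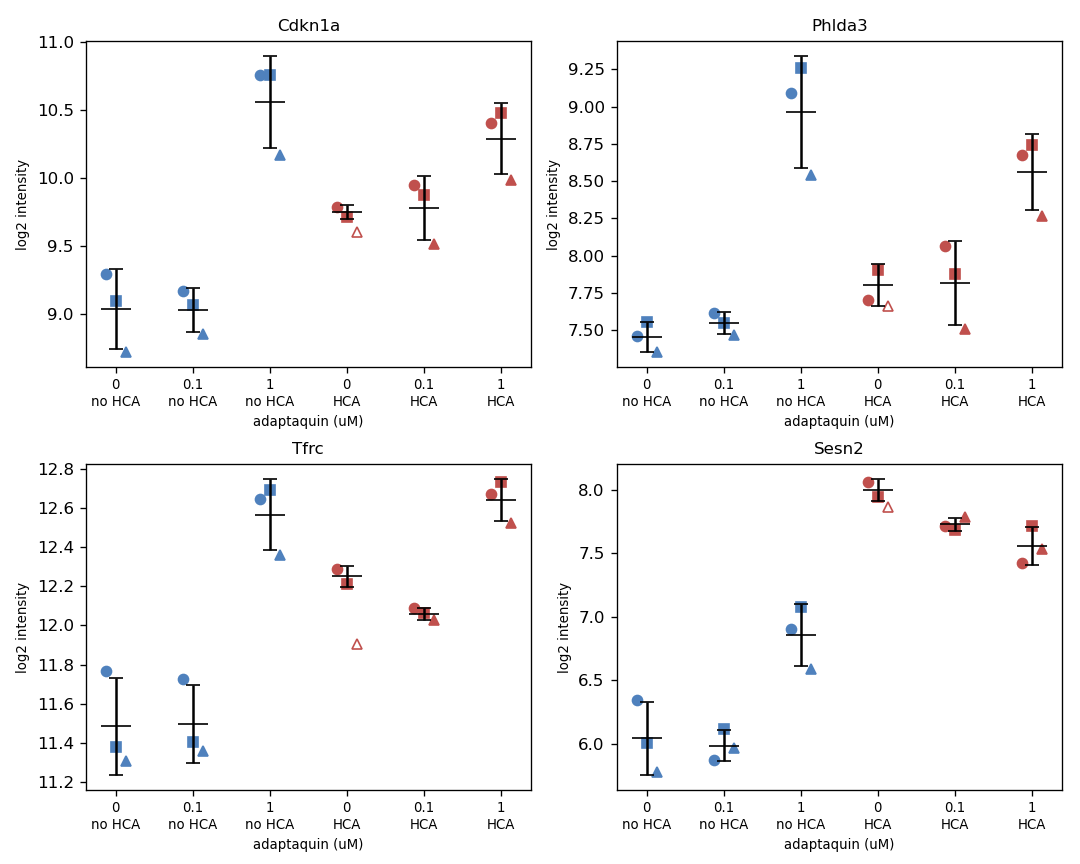
Normalized log2 intensity of Cdkn1a, Phlda3, Tfrc and Sesn2 on each array by adaptaquin dose, without HCA in blue and with HCA in red, where circles, squares and triangles are replicates 1, 2 and 3, bars are the mean and SD, and the open triangle is the array titled as an outlier, which is in no mean. Cdkn1a went from a mean of 9.04 in untreated neurons to 10.56 with 1 µM adaptaquin, and Tfrc from 11.48 to 12.57.

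Adaptaquin at 0.1 µM without HCA changed 0 genes in limma (86 with an unadjusted p under 0.05). The smallest p belonged to Ccdc177 (0.66 ± 0.16), Tyro3, a receptor kinase gene (at least 1.04-fold higher), and Marchf4, a ubiquitin ligase gene (-0.33 ± 0.09). Cdkn1a, Tfrc and Chac1 had values of -0.0064, 0.012 and -0.11, with 95% intervals from -0.42 to 0.40, from -0.27 to 0.30 and from -0.45 to 0.24. All 22 lists had an adjusted p of 0.92 or more, the ATF4 list having a median of 0.010 and the p53 list of 0.018.

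Tested against each other without HCA, the doses differed at 11 genes, all higher at 1 µM, with 0 lower and 234 at an unadjusted p under 0.05 in limma. They included Cdkn1a (1.53 ± 0.19, adjusted p = 4.1e-03), Pqlc3 (1.61 ± 0.25), Phlda3 (1.42 ± 0.18), Ephx1 (1.37 ± 0.22), Ccng1 (1.16 ± 0.17), Tfrc (1.07 ± 0.13), Sesn2 (0.87 ± 0.15) and the kinase gene Mapkapk3 (at least 1.05-fold). Of 18 p53 targets, 3 were higher and 9 adjusted over the list alone (median 0.45, list adjusted p = 2.6e-19). Other lists that passed were the ATF4 targets, with Sesn2 up over all genes and 1 up and 1 down adjusted over the list alone (median -0.10, list adjusted p = 4.4e-03, adjusted p = 0.134 with an estimated correlation), and, with 0 called members by either adjustment, the endoplasmic reticulum list (median -0.11, list adjusted p = 7.0e-03, adjusted p = 0.380 with an estimated correlation) and the cell death list (median 0.11, list adjusted p = 0.024, adjusted p = 0.117 with an estimated correlation). The blocked fit called 18 up and 3 down, median scaling called 0, and the progenitor list had a median of -0.11 (adjusted p = 0.067, blocked 7.1e-03). The count became 4, 6 and 4 without replicates 1, 2 and 3 of the 0.1 µM group, 6 and 6 without replicates 1 and 2 of the 1 µM group, and 0 without all arrays numbered 1 or 2.

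Adaptaquin at 1 µM in neurons with HCA lowered ATF4 and CHOP targets as a list (3 arrays against 2). Of 29, 25 values were negative, with a median of -0.28 (list adjusted p = 8.8e-12). With median scaling and an estimated correlation the list did not pass (median -0.35, adjusted p = 0.190). The mean change of the list score went from -0.27 ± 0.051 (SE) to -0.37 ± 0.11, the mean of all genes moved by -0.098, and the change relative to all genes stayed near its value (-0.27 and -0.28), while the estimated correlation between members went from 0.0391 to 0.200. No single member passed in limma over all genes, and 1 fell adjusted over the list alone. Cth was at least 1.75-fold lower (means 5.32 and 6.51, adjusted p = 0.998), and Slc7a11 had a value of -0.63 ± 0.20, Slc7a3 of -0.64 ± 0.33, Sesn2 of -0.44 ± 0.16, Atf4 of -0.41 ± 0.33, Chac1 of -0.26 ± 0.18, Ddit3 of -0.14 and Vegfa of -0.19. The ATF4 list score was 8.41 ± 0.070 (SD, n = 3) untreated, 9.64 ± 0.065 (n = 2) with HCA, 9.59 ± 0.079 (n = 3) with HCA and 0.1 µM, and 9.37 ± 0.022 (n = 3) with HCA and 1 µM.

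The p53 list also rose with 1 µM in the presence of HCA. Its median was 0.22, 15 of 18 values were positive, 0 passed over all genes and 1 adjusted over the list alone (list adjusted p = 4.7e-06). Phlda3 had a value of 0.75 ± 0.20, Cdkn1a of 0.54 ± 0.21, which the blocked fit called at 0.69 (adjusted p = 0.038), and Tfrc of 0.39 ± 0.15. The glutathione list had a median of -0.086, with 0 members called over all genes and 1 down adjusted over the list alone (list adjusted p = 8.5e-03), and the endoplasmic reticulum list a median of -0.15 with 0 members called (list adjusted p = 6.5e-03, adjusted p = 0.397 with an estimated correlation). The tRNA synthetases had a median of -0.041 (list adjusted p = 0.15, blocked 0.0225), and the HIF targets of -0.0079 (list adjusted p = 0.69). Over all genes 0 passed in limma, 244 had an unadjusted p under 0.05, and the blocked fit called Cdkn1a alone. The smallest p after Cth belonged to Hyal1, a hyaluronidase gene (at least 1.46-fold higher), and Dcxr (0.76 ± 0.17).

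**Figure D2:**
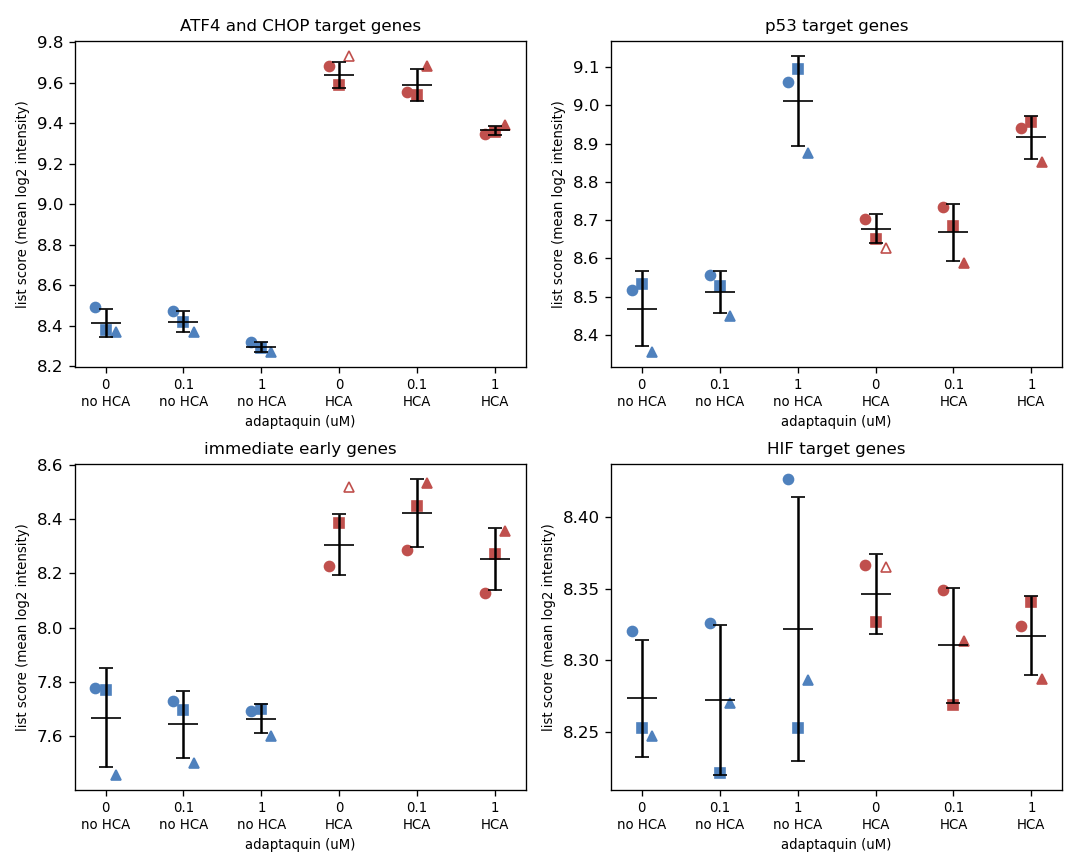
Mean log2 intensity of the members of 4 gene lists on each array by adaptaquin dose, without HCA in blue and with HCA in red, with circles, squares and triangles for replicates 1, 2 and 3, bars for the mean and SD, and an open triangle for the array titled as an outlier, which is in no mean. The ATF4 score was 9.64 with HCA and 9.37 with HCA and 1 µM adaptaquin, and the p53 score was 8.47 in untreated neurons and 9.01 with 1 µM adaptaquin.

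At 0.1 µM with HCA, 0 genes passed in limma (274 with an unadjusted p under 0.05) and 0 lists passed. The smallest p belonged to Oxsr1, a stress kinase gene (-0.62 ± 0.13), Cldn9, a tight junction gene (at least 1.48-fold higher), and Exosc6, a gene of the RNA exosome (0.56 ± 0.14). The ATF4 list had a median of -0.034 (list adjusted p = 0.56), Chac1 had a value of 0.11 with an interval from -0.28 to 0.50, and Slc7a11 of -0.075 with an interval from -0.51 to 0.36. The microglia score was higher by 0.10 with no overlap of the groups (list adjusted p = 0.46).

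Between the doses with HCA, ATF4 and CHOP targets were lower at 1 µM than at 0.1 µM. Of 29 values 26 were negative, with a median of -0.23 (list adjusted p = 2.4e-11) and 0 called members by either adjustment, Chac1 having a value of -0.37 ± 0.16. The p53 list was higher, with a median of 0.20, 0 members over all genes and 2 adjusted over the list alone (list adjusted p = 7.3e-08). Lists with 0 called members that passed at the preset correlation, with list adjusted p between 5.5e-03 and 0.021, were the glutathione genes (median -0.041, adjusted p = 0.057 with an estimated correlation), the tRNA synthetases (-0.13, adjusted p = 0.157 with an estimated correlation), the immediate early genes (-0.17, adjusted p = 0.219 with an estimated correlation), the microglia markers (-0.22, adjusted p = 0.219 with an estimated correlation) and the cholesterol genes (0.13, adjusted p = 0.516 with an estimated correlation). Over all genes 0 passed in limma and 234 had an unadjusted p under 0.05. The smallest p belonged to Plaur, the urokinase receptor gene (0.88 ± 0.17), Mapkapk3, which was too dim for a value, and the matrix proteoglycan gene Dcn (-0.71 ± 0.16).

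The interaction tested whether 1 µM adaptaquin acted differently with HCA. Over all genes 0 passed in limma, with 154 at an unadjusted p under 0.05. Sesn2 had the smallest p (-1.26 ± 0.22, adjusted p = 0.44), its value being positive for adaptaquin alone and negative with HCA, followed by the mitochondrial ribosome gene Mrpl39 and Cth, for which no value is given because neither was above background in all 4 groups. Cdkn1a had a value of -0.98 ± 0.29, Phlda3 of -0.75 ± 0.27, Tfrc of -0.69 ± 0.20, Chac1 of 0.0092 ± 0.24 and Slc7a11 of 0.0071 ± 0.27. These values set HCA-only arrays numbered 1 and 2 against groups that also hold number 3, so differences between replicate numbers enter them. In untreated neurons Cdkn1a was 9.30, 9.10 and 8.72 in replicates 1, 2 and 3. The p53 list was lower, with a median of -0.31 and 12 of 18 values negative, 0 of them called by either adjustment (list adjusted p = 3.7e-04), but not without all arrays numbered 1 (-0.21, adjusted p = 0.250). The ATF4 list had a median of -0.056 (list adjusted p = 1.8e-03, adjusted p = 0.0806 with an estimated correlation), with 2 members down adjusted over the list alone. Its call was lost without HCA replicate 1 (adjusted p = 0.0873) and without all arrays numbered 1 (adjusted p = 0.250), and its median ran from -0.17 to -0.032 over the arrays left out. The glutathione list had a median of -0.10 (list adjusted p = 0.026, adjusted p = 0.0806 with an estimated correlation), with 1 member down adjusted over the list alone, and the cell death list, with 0, of -0.077 (list adjusted p = 0.040, adjusted p = 0.0806 with an estimated correlation). At 0.1 µM the interaction passed for 0 genes in limma, with 163 at an unadjusted p under 0.05, and for 0 lists. Cldn9 had the smallest p, followed by the protocadherin gene Pcdhgc3 (-0.96 ± 0.23) and Hyal1, and no value is given for Cldn9 and Hyal1 because neither was above background with HCA alone.

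**Figure D3:**
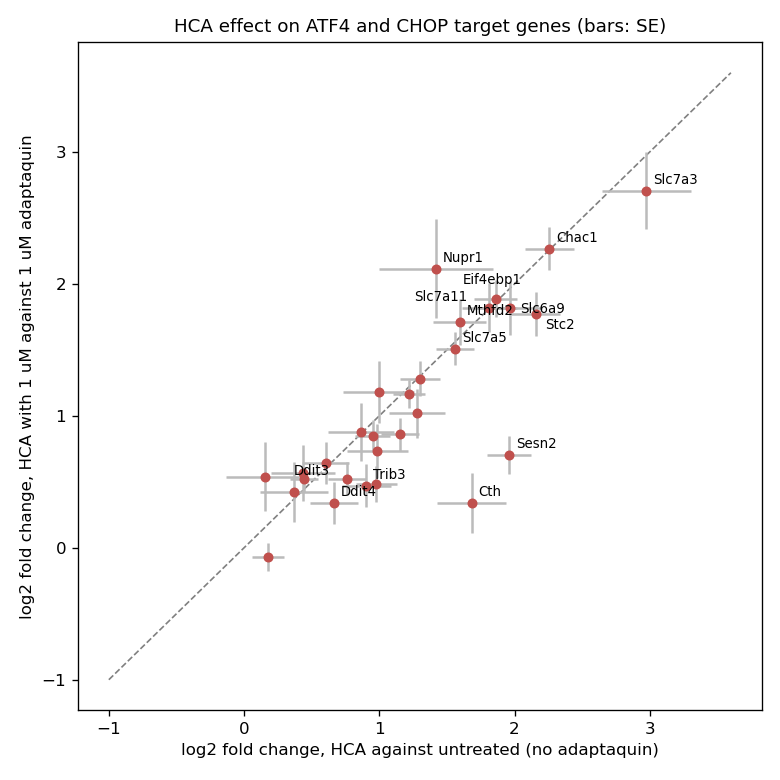
Log2 fold change (with SE bars) of each of 29 ATF4 and CHOP targets under HCA without adaptaquin on the horizontal axis and under HCA with 1 µM adaptaquin on the vertical axis, with the line of equal change dashed. Of the 29 points 17 lie below the line, Sesn2 at 1.96 and 0.70 and Chac1 at 2.26 and 2.27. The points of Atf3, Cebpg, Cth and Trib3 rest in part on groups in which the gene was not above background.

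Opposite changes under HCA and under adaptaquin were looked for across all genes. The HCA effect and the adaptaquin effect with HCA share the HCA-only arrays, and their correlation across genes, which are not independent replicates, was -0.464 at 0.1 µM and -0.485 at 1 µM. In 100 simulations with no effect of either treatment and no pairing of replicate numbers it averaged -0.604 for both doses, and the observed covariance minus the simulated one was 0.00692 and 0.00566. With the replicate effects of the blocked fit kept, chosen after the data were seen, it averaged -0.685 at both doses, and the covariance difference was 4.3e-06 and -0.00122. The simulated genes had no HCA effect, whose spread enters the observed correlations but not the simulated ones. The observed and simulated correlations therefore cannot be compared in size, and only the covariances were set against each other. With the 2 HCA-only arrays used 1 in each effect, the correlations were -0.104 and -0.0997 at 0.1 µM, and 0.00751 and -0.200 at 1 µM. The effects of 1 µM adaptaquin with and without HCA, which share no array, correlated at 0.202, and 12 of the 13 genes called without HCA had the same sign with it. For the dose difference the correlation was 0.221, and 10 of 11 genes had the same sign.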

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

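All explanations weighed here were tested only after the results had been seen, and the splits of the arrays were chosen before.

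For 1 µM adaptaquin, 4 gene lists passed the test of the difference between its effects with and without HCA, at the preset correlation. They stand here for that reason, although 0 single genes passed that test. The median differences on the log2 scale were -0.056 for ATF4 and CHOP targets, -0.10 for glutathione genes, -0.31 for p53 targets and -0.077 for cell death genes. With an estimated correlation the p53 list alone passed (adjusted p = 0.0434), and each of the other 3 lists had an adjusted p of 0.0806. Over the arrays left out the p53 median ran from -0.37 to -0.21, and the p53 call at the preset correlation did not hold in all of them. These values set HCA-only arrays numbered 1 and 2 against groups that also hold number 3, so differences between replicate numbers enter them. The array titled as an outlier, which was left out of the comparisons, stands here because its ATF4 score of 9.73 lay above the highest score of 8.49 among arrays without HCA.

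The first pattern was the rise of p53 targets at 1 µM without HCA. A batch that follows the replicate number was argued against. Within replicate numbers 1, 2 and 3 the list score rose by 0.55, 0.56 and 0.52, the smallest being 0.52 with an SD of 0.020. A batch that parts the groups in the same way within each number cannot be told apart from the treatment, since no slides are named. A change of cell mix was weighed by the upper limit of the change of every cell type list tested, 2 SE above its value. Every limit lay below the p53 median of 0.44, the highest being 0.40 for the 7 vessel and fibroblast markers (SE 0.22). That margin does not decide the question for these markers, since the p53 median was 0.36 without replicate 3 of the 1 µM group. The SE also ignores the pairing by replicate number, so it holds the spread between numbers. The score of these markers differed by -0.043, and it ranged from 7.33 to 7.86 in untreated neurons and from 7.29 to 7.79 with 1 µM. These values show no rise, but the limit was not computed within replicate numbers. The next highest limit was 0.20, for proliferating progenitors, which argues against a rise of the other marker lists as large as that of the p53 list. The microglia score differed by -0.15 with no overlap of the groups. The list test with an estimated correlation, run in 4 other normalizations (medians from 0.26 to 0.44), ended the call only under median scaling (adjusted p = 0.0603, median 0.35), where the list score change went from 0.54 ± 0.066 (SE) to 0.46 ± 0.16, all genes moved by -0.074, and the rise over all genes was 0.54 against 0.55. A comparison with genes of like brightness was chosen after that. Its smallest excess over 5 normalizations and 3 replicate numbers was 0.30 (SD up to 0.048). That argues only against a scaling that moves genes of like brightness together. The list was followed because it had moved against all genes, so the excess is no separate evidence of the rise.

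The second pattern was the lowering of ATF4 targets by 1 µM adaptaquin in the presence of HCA. Chance height of the 2 HCA-only arrays was argued against, since the lowest score with HCA and 0.1 µM lay 0.15 above the highest with HCA and 1 µM. The list test (medians from -0.35 to -0.21) again ended the call only under median scaling (adjusted p = 0.190), where the score change went from -0.27 ± 0.051 (SE) to -0.37 ± 0.11, all genes moved by -0.098, and the change relative to all genes was -0.28 against -0.27, so the call ended with a wider spread and not with a smaller fall. The comparison with genes of like brightness, chosen after that, left a fall in each of 5 normalizations in replicate numbers 1 and 2. The smallest was -0.18 (SD up to 0.089, each from 2 values). That argues only against a scaling that moves genes of like brightness together, and it is no separate evidence of the fall, since the list had already moved against all genes. A lowering that does not need HCA cannot be told apart from one that does, since the interaction of the list had an adjusted p of 0.0806 with an estimated correlation and the list without HCA had a median of -0.11.

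The third pattern was the array titled as an outlier. A culture without HCA under a wrong label was argued against, since its ATF4 score lay 1.24 above the highest array without HCA. Loss of neurons stayed open, since its neuron marker score lay 0.15 above the lowest other array, and a score of markers with a high level can keep its level when cells are lost. Low signal remained, with an upper quartile of intensity at 72.5% of the lowest other array, although its median intensity of 133 lay within the range of 130 to 184 of the other arrays.

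Other splits of the 6 arrays of a comparison into 3 and 3 were counted, but 10 splits are too few for a share under 0.05. The HCA effect at 0.1 µM called 170 genes against at most 0 in the other splits, and at 1 µM it called 106 against at most 1, so that 1 split, the real one, reached each count. Adaptaquin at 1 µM without HCA called 13 against 0, and the dose difference without HCA called 11 against 1, which came from a split that parts every pair of replicate numbers as the real one does. Adaptaquin at 0.1 µM without HCA and the dose difference with HCA called 0 in limma, as did all 10 splits (86 and 234 genes with an unadjusted p under 0.05).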

How the results depend on the processing

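Leaving out each replicate number, the 17 arrays normalized alone, and the combinations of the blocked fit with all 18 arrays or with an estimated correlation were chosen after the data were seen, as was the choice of list results followed here. No called named gene reversed its direction under any setting run for it, and no called list did in 14 settings, while leaving out arrays was followed for only 13 list results. Among values near 0 that were not called, some changed sign, such as the HIF lists at 1 µM with an array left out, the interaction of Chac1 at 1 µM of 0.0092, which was -0.083 in the blocked fit and -0.11 with all 18 arrays, and the separate-array correlation at 1 µM of 0.00751, which was -0.00570 with no background correction, -0.00769 with median scaling and -0.00536 in the authors' table. Of 120 calls of named genes, 106 held with all 18 arrays, 115 with array weights, 120 in the blocked fit, 107 with no background correction, 65 with median scaling, 98 with no filter, 38 with only the groups of the contrast, and 43, 26 and 46 without all arrays numbered 1, 2 and 3. The blocked fit called 59 more of the named values. Of 43 list calls, 40 held with all 18 arrays, 38 with array weights, 42 in the blocked fit, 42 with no background correction, 41 with median scaling, 42 in the authors' table, 38 with no filter, 31 with detection on every array, 40 with the mean of probes, 41 with only the groups of the contrast and 19 with an estimated correlation. The 24 calls lost with an estimated correlation alone are given with that p beside them. A p from an estimated correlation combined with median scaling or the blocked fit is a separate setting. The dimmest genes limit the results, since a change in a gene near background is seen only as a bound. A slide block was not run, since no slides are named. The largest shift of the median of all genes under any setting was 0.0924.

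The number of genes called for HCA without adaptaquin (67) became 114 with all 18 arrays, 205 with array weights, 252 in the blocked fit, 114 with no background correction, 39 with median scaling, 115 in the authors' table and 22 with only its own groups. The number for HCA at 0.1 µM (170) became 533 in the blocked fit, 54 with median scaling, 111 with no filter, where more genes were tested, and 43 with only its own groups. The number for HCA at 1 µM (106) became 402, 42 and 14 in the blocked fit, with median scaling and with only its own groups. For 1 µM adaptaquin without HCA the 13 genes became 21 in the blocked fit, 0 with median scaling or only its own groups, 7 with no filter and 8 with detection on every array. For the dose difference without HCA the 11 genes became 21 in the blocked fit and 0 with median scaling or only its own groups. For 1 µM with HCA the blocked fit called 1. The blocked fit with all 18 arrays called 469, 472 and 371 genes for HCA at 0, 0.1 and 1 µM, 22 for 1 µM without HCA, 17 for the dose difference, 5 for 1 µM with HCA and 1 for the interaction at 1 µM. The blocked fit removes the differences between replicate numbers, and fits of only the groups of a contrast have fewer samples. The cause was not tested for the other changes.

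The ATF4 list in the interaction at 1 µM lost its call with detection on every array (-0.054, adjusted p = 0.0979), with an estimated correlation (-0.056, 0.0806) and in the blocked fit with an estimated correlation (-0.088, 0.109). For 1 µM without HCA it lost its call with an estimated correlation (-0.11, 0.240) and in the blocked fit with one (-0.11, 0.200). The immediate early list for HCA lost its call in the blocked fit with an estimated correlation (0.37, 0.0706). The blocked fit changed no other call of a gene or list named here than those given beside the results. The mean correlation of separate arrays at 0.1 µM (-0.102) was -0.140 with no background correction, -0.0965 with median scaling, -0.139 in the authors' table, -0.0681 with no filter and -0.146 with detection on every array, and the cause was not tested.

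With 1 array or 1 replicate number left out, counts ran from 7 to 65 for HCA without adaptaquin, from 22 to 112 at 0.1 µM, from 15 to 122 at 1 µM, from 0 to 14 for 1 µM without HCA, from 0 to 10 for the dose difference without HCA, and stayed at 0 in limma for the other 6 contrasts. List medians for HCA ran from 1.10 to 1.25, from 0.98 to 1.10 and from 0.80 to 0.96 for ATF4 targets at the 3 doses, and from 0.22 to 0.47 for immediate early genes. For 1 µM without HCA they ran from -0.15 to -0.057 for ATF4, from -0.029 to 0.083 for HIF and from 0.36 to 0.47 for p53 targets. For 1 µM with HCA they ran from -0.30 to -0.22, from -0.029 to 0.022 and from 0.19 to 0.26. The ATF4 dose difference with HCA ran from -0.27 to -0.18, and the interactions ran from -0.17 to -0.032 for ATF4 and from -0.37 to -0.21 for p53 targets. Where an arm kept 1 array, that array was assumed to vary like the other groups.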

Other observations

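The remaining lists describe the cells under HCA without adaptaquin, and 0 of their members were called in limma, over all genes or, with the exceptions given, adjusted over the list alone. Neuron markers had a median of -0.00073 over 23 genes (list adjusted p = 0.33, mean 0.051, test upward) and GABAergic neuron markers of 0.058 over 9 (0.45). Respiratory chain genes had a median of 0.00053 over 35 (0.99, mean -0.016), and heat shock genes of 0.062 over 17 (0.22), with 1 up adjusted over the list alone. Interferon genes had a median of -0.26 over 7 (0.59), microglia markers of 0.071 over 9 (0.73), vessel and fibroblast markers of 0.14 over 7 (0.59), and oligodendrocyte markers of -0.16 over 6 (0.24), with 1 down adjusted over the list alone. Cell death genes had a median of -0.083 over 17 (0.82), with a mean of 0.030. The list of the prolyl hydroxylases with their transcription factors had a median of 0.053 over 8 genes (0.68), with 1 up and 1 down adjusted over the list alone.

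Single genes, of these lists or of none of them, moved under HCA at an adaptaquin dose against that dose alone. Hspa9, a heat shock list member that encodes a mitochondrial chaperone, rose by 0.36 ± 0.072 at 0.1 µM (adjusted p = 0.020). It had a value of 0.36 without adaptaquin (adjusted p = 0.056, blocked 0.016). Mt3, a metallothionein gene of neurons and glia, fell by 0.65 at 0.1 µM and by 0.71 at 1 µM. Hdac1 fell by 0.80 ± 0.13 at 1 µM. Under 1 µM adaptaquin without HCA, Slc19a2, a thiamine transporter gene, and Mapkapk3 were also called, and they are named here after their values were seen.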
